A study of Arabidopsis thaliana with 6 samples.

How the data were processed

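Total RNA from mature pollen of Arabidopsis thaliana was measured on 6 Affymetrix ATH1 arrays, 2 for each of 3 groups. The groups, taken from the sample labels, were wild-type Col-0, an insertion line of the SAIL collection (SAIL_1168_C11, called the TF1 line in the labels' terms) and an insertion line of the SALK collection (SALK_018864, the TF2 line). Per the labels, plants were raised on compost, in a growth room at 21 °C and 75% humidity, RNA was extracted with a Qiagen column kit, and biotin-labelled targets were made by the one-cycle protocol. The labels do not say whether the replicates came from separate plants or separate pollen collections, so every p-value measures only the spread between these samples, which may be technical.

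The deposited values are array signal intensity on a linear scale, 1 value per probe set and array. MAS5 and GCOS are named by the submitters' processing notes; their versions and settings are not given in the sources used here. The authors' scaling was read from the values: the mean signal after trimming 2% at each end lay at 100.0 on every array, and this scaling was kept. The table carries no present or absent calls. No columns were left unmapped, and the number of arrays limits the precision.

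The table held 22810 probe sets, of which 64 Affymetrix control probe sets (AFFX) stayed out of the tests. In the probe annotation used here 13513 probe sets had 1 gene, 503 had several and 8730 had none listed. The unlisted ones are unnamed here, not without a gene, and no gene was named from a probe set with several. Of the probe sets with 1 gene, 13436 were matched to a RefSeq gene table (assembly TAIR10.1), which was used for names and gene order only. The named part is uneven: 14.6% of the coding genes that carry a symbol, and 63.1% of those known by locus only, had a probe set of their own, so the gene lists are covered in small part.

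Signals were tested as log2(signal + pseudocount), with the 25th percentile of all values, 10.3, as the pseudocount. All fold changes are on this scale, which understates the change of dim genes. Probe sets were kept whose mean log2 value over the 6 arrays was at or above the median of all probe sets, which left 11373, of which 6280 had 1 gene. The 6 arrays were fitted together in limma (lmFit, then eBayes with an intensity trend), so that the 3 groups shared an estimate of the spread. All adjusted p-values for probe sets are limma's after Benjamini-Hochberg adjustment within a comparison, with 0.05 as the threshold, and all tests were two-sided. Exact permutation of 2 arrays against 2 could not pass that threshold, so no such test was run.

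The comparisons, the test, the filter, the pseudocount rule, 20 gene lists, the rule for naming genes and all but 1 of the alternatives were chosen before the data were examined. The rule took, for each comparison, the 10 highest and 10 lowest changes among probe sets with 1 gene that passed the threshold with both arrays of a group above both of the other, then up to 4 members of each list past the threshold, by size, and BZIP34. REN1, also in the rule, is not analysed here. Any gene named outside it is said to be so.

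The lists covered vegetative cell and pollen tube growth, the sperm cell, pectin-modifying enzymes, callose and cellulose synthases, sugar transporters, cation and proton transport, ABC transporters, lipid metabolism, lipid transfer and oleosins, sporopollenin synthesis and tapetum, heat shock and protein folding, cytosolic ribosomal proteins, the nucleolus and ribosome biogenesis, late embryogenesis abundant and desiccation proteins, cell wall glycoproteins and wall-loosening enzymes, pollen-expressed transcription factors, leaf and photosynthesis, flower and other sporophytic tissue, cell cycle and histones, and defence and jasmonate. Members were matched by symbol or synonym. Lists written as word patterns were meant for gene descriptions, which the gene table lacks, so the patterns were matched to symbols and synonyms. The probe annotation then left few of the genes they took. It named 6 of 267 lipid metabolism genes, 0 of 131 ABC transporters and 44 of 188 cell wall genes. Lists with at least 5 kept members, 1 probe set per gene, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's rotation test fry were run beside it. With an estimated correlation, camera also judges its statistic on the few residual degrees of freedom of the fit, which by itself raises p-values. Fry asks whether a list changed at all, and camera whether it changed more than the other genes. Plastid-encoded genes, mitochondrion-encoded genes, 26 families defined by the prefix of their symbol and a list of seed coat markers were added after the values were seen.

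Both lines were compared with the same wild-type arrays. The overlap of their changes was therefore set beside 100 simulations of unchanged groups sharing those controls and beside the overlap of independent lists. With 2 controls no split that keeps 2 in each part was possible. The test was also run on simulated data with known changes. For the TF1 line against wild type, 21% of changes of 1 log2 unit and 61% of changes of 2 log2 units were recovered, and 5.75% of calls were false, over 11373 probe sets. For the TF2 line against wild type these were 18%, 63% and 3.57%, over 11373 probe sets. Only 100 probe sets per size of change and line were altered, far fewer than were called in the data. Recovery depends on that number, so these rates do not carry over to the data. The noise was normal with the spread of the same trended fit, so the share of false calls could not test the trend.

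Alternatives were 0.25 times and 4 times the pseudocount, no filter and a filter to the top 25%, quantile normalization, median centring, the replicate number as a block, eBayes without the trend, robust eBayes, only the 2 groups compared, and each array left out in turn. A fit without organelle-encoded and leaf list genes was added after the data were seen. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.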

Results

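The series measured gene expression in mature pollen of 2 Arabidopsis insertion lines and of wild type, under a title that names transcription factors of the gametophyte. Pollen is the male gametophyte, a vegetative cell that grows the pollen tube and encloses a pair of sperm cells. Each group had 2 arrays, and values below are mean signals ± SD (n = 2 arrays per group) in units of array intensity. Median signal per array lay between 33.6 in TF1 line replicate 1 and 43.0 in wild type replicate 2. The 100 brightest probe sets took 30.5% to 39.6% of the total signal, with the wild-type arrays at 31.3% and 30.5%. Across kept probe sets, which are not independent replicates, log2 signals of replicate arrays correlated at 0.948 in wild type, 0.917 in the TF1 line and 0.908 in the TF2 line, and arrays of different groups at 0.755 to 0.883.

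The control probe sets for the 3′ and 5′ ends of housekeeping transcripts differed between groups. The actin 3′ probe set read 595 and 699.8 on the wild-type arrays, 220.2 and 231 on the TF1 arrays and 99.6 and 138 on the TF2 arrays. The GAPDH 3′ probe set read 794 and 719 in wild type, 229.6 and 225 in TF1, and 92.6 and 139 in TF2. The log2 ratio of 3′ to 5′ signal, a sign of RNA quality, was 2.18 and 1.80 for actin in wild type, 1.98 and 0.86 in TF1, and 0.14 and 1.101 in TF2. For GAPDH it was 2.33 and 2.40, 1.68 and 0.77, and 0.91 and 2.16 in the same order. The 5′ probe set of GAPDH read 158 and 137 in wild type, 71.5 and 132 in TF1, and 49.2 and 31.2 in TF2. That of actin read 131 and 201, 55.7 and 128, and 90.6 and 64.1. In these pairs both ends were lower on every array of the lines, so the ratios cannot be read as RNA quality alone. For ubiquitin the ratio stayed between −0.05 and 0.68 on all arrays. The array carries another pair for each control: in the same order the ratios were 2.58 and 2.91, 0.63 and 0.15, and −1.29 and −2.04 for actin, and −0.21 and 0.85, 0.34 and 0.70, and 0.05 and 0.28 for GAPDH, with 1.48 to 1.82 for ubiquitin.

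SALK_018864 is known outside the labels as an insertion line of BZIP34, a bZIP transcription factor of pollen, whereas the gene hit in the TF1 line is not given in the sources used here. BZIP34 signal was close to the median signal of the arrays in wild type, at 45.6 ± 14.3, and in the TF1 line, at 43.8 ± 22.7. In the TF2 line BZIP34 lay above that median, at 126 ± 3.63. It was higher in TF2 than in wild type, by 1.304 log2 units (SE 0.46, adjusted p = 0.0479), a call that was lost without the filter on dim probe sets (adjusted p = 0.0848), without the trend (0.0655), with the smaller pseudocount (0.0622) and without wild type replicate 1 (0.256), wild type replicate 2 (0.0929), TF2 line replicate 1 (0.130) or TF2 line replicate 2 (0.112). Between the lines the difference was 1.395 (adjusted p = 0.119), and between TF1 and wild type −0.09 (adjusted p = 0.925). Where the probes lie relative to the insertion is not known here, so this probe set checks nothing about the labels.

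The first comparison asked which transcripts differed between TF1 and wild-type pollen. Among probe sets with 1 listed gene, which all rankings here are limited to, the steepest fall was that of AT1G70790, which encodes a C2-domain protein and is among the bright transcripts of wild-type pollen: it dropped from 12012 ± 555 to 594 ± 73.4 (log2 change −4.32, SE 0.13, adjusted p = 3.66e-09). RCA, which encodes Rubisco activase, went from 1681 ± 89.1 to 93.4 ± 17.9 (−4.04, SE 0.20, adjusted p = 4.05e-07), and the antenna protein gene LHCB4.2 from 380.3 ± 11.8 to 11.2 ± 5.19 (−4.20, SE 0.56, adjusted p = 0.000245). The steepest rise among them was that of AT3G06150, from 429 ± 80.1 to 3304 ± 35.6 (2.93, SE 0.15, adjusted p = 4.05e-07), and JMT, which encodes a jasmonic acid methyltransferase and is also among the 10 largest rises, went from 248 ± 5.31 to 1208 ± 148 (2.23, SE 0.15, adjusted p = 2.44e-06).

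Among the other named genes with the largest rises in TF1, AT5G20390, of a glycosyl hydrolase family, reached 11933 ± 670.2 from 2329 ± 4.60 (2.35). AT2G19050, of the GDSL lipase family, rose by 2.48, AT4G33860 by 2.37, AT4G14810 by 2.33 and AT1G67640 by 2.32. XPO1B, which encodes an exportin, rose from 24.3 ± 18.1 to 169 ± 14.9 (2.48). AT1G17545 and AT4G28940 also passed the threshold (2.18 and 2.13) from wild-type signals near the pseudocount, and these calls did not hold under every alternative. Besides the genes above, the largest falls among probe sets with 1 gene were in the plastid genes ndhJ (−3.95) and atpH (−3.84), in SBPASE of the Calvin cycle (−3.68), in HPR of photorespiration (−3.89), and in AT1G78020 (−3.78), AT1G65490 (−3.68) and ECS1 (−3.61).

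All 9 measured genes of the leaf and photosynthesis list fell in TF1, 9 adjusted over the list alone, with a median log2 change of −3.02. Their wild-type signals ran from 380.3 for LHCB4.2 to 1681 for RCA. The list was called by camera (adjusted p = 1.35e-12) and with an estimated correlation (adjusted p = 0.0191). Of 68 plastid-encoded genes, a group added after the values were seen, 67 fell, with a median of −2.44 (camera adjusted p = 1.80e-49; adjusted p = 0.119 with an estimated correlation). Of 12 measured pollen-expressed transcription factors, 7 rose, 7 adjusted over the list alone, and the median was 0.61. AGL18 went from 2529.7 ± 10.9 to 5279.5 ± 770.0 (1.05), AT2G40620, known as BZIP18, rose by 0.99, AGL65 by 0.80 and AGL104 by 0.79. The call of this list (camera adjusted p = 0.00806) was lost with an estimated correlation (adjusted p = 0.113). That estimate was −0.0055, below the preset 0.01, so it was the fewer degrees of freedom that raised the p-value.

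**Figure D1:**
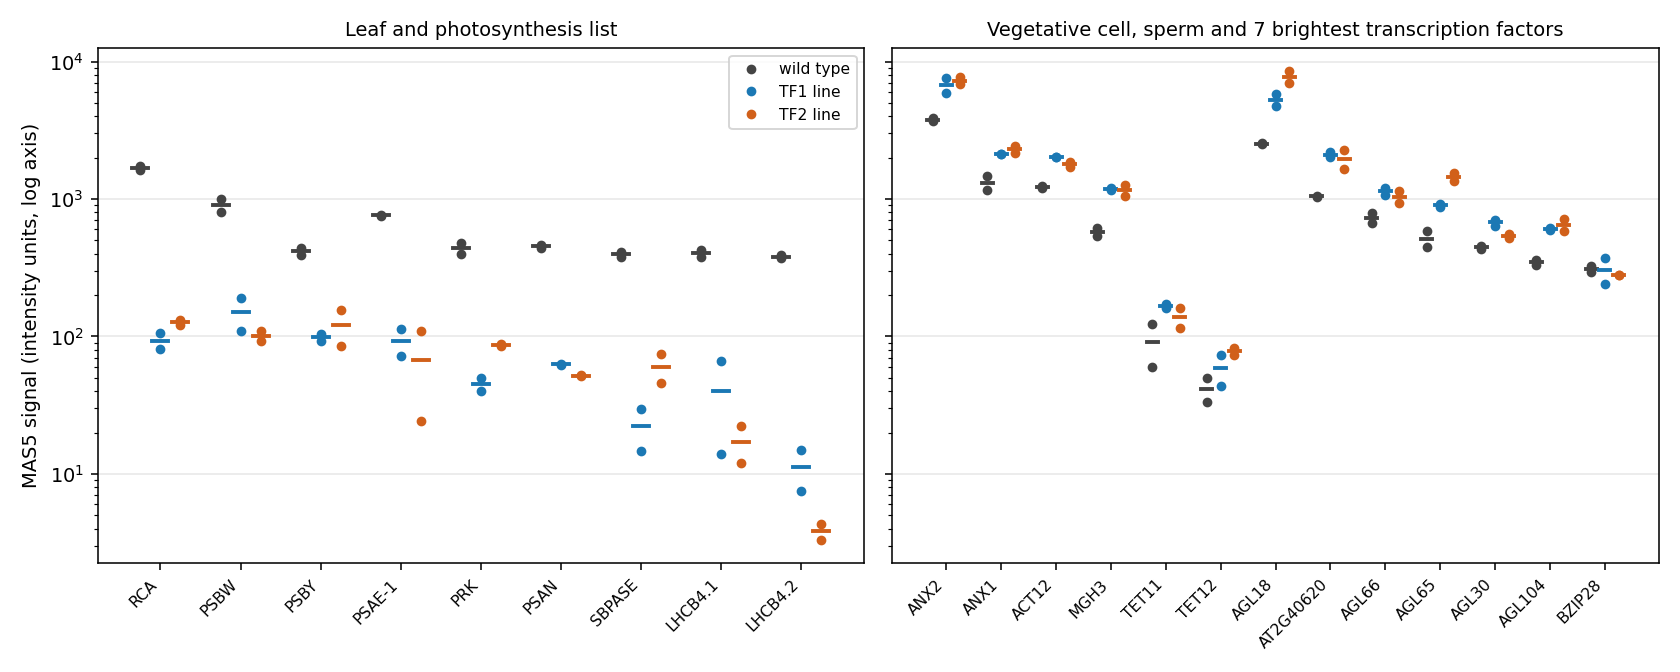
Array signal (intensity units, log axis) of the 9 leaf and photosynthesis genes and of vegetative cell, sperm and transcription factor genes; points are arrays, bars are means of 2 arrays. The leaf genes read 380.3 to 1681 on average in wild type, and all 9 were lower in both lines.

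Cell wall genes moved both ways in TF1. Of 29 measured, 7 rose and 4 fell (7 and 4 adjusted over the list alone), and the list was not called by camera (median 0.38, adjusted p = 0.124) but was by fry, upward (adjusted p = 0.00924). The falls were those of XTH18 (−1.96), XTH19 (−1.84), EXGT-A3 (−1.71) and EXLA1 (−1.48). The rises, named after their values were seen, were smaller: GH9A4 (1.42), EXPA4 (1.21), GH9B11 (1.02), EXPA16 (1.00), BGAL16 (0.91), EXPB5 (0.89) and EXPA24 (0.82). Of 13 sugar transporters, TMT1 of the vacuole membrane rose (0.80) and SWEET8 (−1.08) and AtVEX1 (−0.86) fell, 1 and 2 adjusted over the list alone (median −0.53; adjusted p = 0.109 by camera and 0.00646 by fry, downward). The actin 3′ and GAPDH 3′ controls and the leaf list fell on the same arrays as these genes. All 3 vegetative cell genes rose, 3 adjusted over the list alone: the receptor kinase genes ANX2 (0.82) and ANX1 (0.70), which maintain pollen tube integrity, and the actin gene ACT12 (0.72). After quantile normalization, however, their median was 0.14 and none of the 3 calls held. Of 3 sperm genes, the histone H3 gene MGH3 rose from 577 ± 57.0 to 1184 ± 36.9 (1.03; 2 genes adjusted over the list alone).

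The remaining lists had few measured members in TF1 against wild type, and their counts are given with those adjusted over the list alone in brackets. Of 4 cation and proton transporters, CHX6B rose (1.01) and CHX19 fell (−1.32) [2 higher, 1 lower]. Of 2 pectin-modifying enzymes PMEPCRF fell (−1.44) [2 lower], of 3 lipid metabolism genes the sterol glucosyltransferase gene SGT rose (0.86) [1 higher], of 4 late embryogenesis abundant genes AT2G44060 fell (−1.67) [1 lower], and of 3 sporopollenin and tapetum genes SWEET8 fell [1 lower]. MGH3 was the 1 of 2 cell cycle and histone genes that rose [1 higher]. No gene passed the threshold in limma among 3 heat shock genes [0], 1 nucleolar gene [1 lower], 1 lipid transfer gene [0], 1 flower gene, DFR [1 higher], and 2 defence genes [0]. The callose and cellulose, ABC transporter and cytosolic ribosomal lists had 0 kept members in all comparisons.

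In all, 2453 of 11373 probe sets differed between TF1 and wild type in limma, 1357 higher and 1096 lower, and 3644 had an unadjusted p under 0.05. Among those with 1 gene, 785 were higher and 486 lower. Over all called probe sets, 21 rose and 382 fell at least 4-fold. The count was 456 (75 higher, 381 lower) without the intensity trend, 1374 (415 lower) without wild type replicate 1 and 1266 (819 higher, 447 lower) without wild type replicate 2. Median centring gave 1779 higher and 766 lower, as it moved the median change of all tested probe sets from −0.02 to 0.21 (0.11 under quantile normalization). Without the trend, the genes named above by the rule from lists other than the leaf list lost their calls, except XTH19, as did HPR and AT4G28940. Leaving out a single array also ended the calls of ANX1, AGL65, CHX19, SGT, TMT1, EXLA1, XTH18, XTH19, EXGT-A3, PMEPCRF, AT2G44060, AT1G17545 and AT4G28940 in at least 1 case each.

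The second comparison asked the same of TF2 and wild-type pollen. A plastid transcript, that of atpH, fell below the pseudocount, and GILT, which encodes a thiol reductase, fell to low signal. The plastid gene atpH, for a subunit of ATP synthase, went from 1233 ± 138 to 3.31 ± 1.28 (log2 change −6.51, SE 0.41, adjusted p = 4.28e-07) and GILT from 1275 ± 25.3 to 24.5 ± 15.7 (−5.28, SE 0.26, adjusted p = 6.79e-08). JMT rose to 1859 ± 210.4 (2.85, SE 0.15, adjusted p = 1.05e-07), and AT4G22490, of the lipid transfer protein superfamily, went from 2715 ± 139.6 to 16271 ± 1663 (2.58, SE 0.12). The leaf list and the actin and GAPDH 3′ controls were low here as well.

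Among probe sets with 1 gene, the other largest falls in TF2 were in the plastid genes rps4 (−5.85), rps19 (−5.61), psaI (−4.88), psaJ (−4.88) and petG (−4.84), in AT1G62480 (−5.26), in EXO, a gene of cell expansion, which went from 551 ± 32.6 to 5.17 ± 0.0548 (−5.18), and in AT2G19970, of the CAP secreted protein family (−5.08). The other largest rises among them were in AT5G14830 (2.88), AT4G28940 (2.85), AT4G14810 (2.72), AT4G33860 (2.70), AT2G19050 (2.66), AT5G20560 (2.66), AT1G28710 (2.63) and AT5G20390 (2.63). AT5G20390 read 14529 ± 1105 in TF2.

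In TF2 all 9 leaf genes were again lower, 9 adjusted over the list alone, with a median of −3.03 (camera adjusted p = 1.38e-09; adjusted p = 0.0291 with an estimated correlation). LHCB4.2 fell by 4.79, LHCB4.1 by 3.94, RCA by 3.62 and PSAE-1 by 3.58. Of 68 plastid-encoded genes 67 fell, with a median of −3.85 (camera adjusted p = 3.38e-50; adjusted p = 0.116 with an estimated correlation). Of 12 transcription factors 6 rose, 7 adjusted over the list alone, and the median was 0.64. AGL18 reached 7733 ± 1033 (1.60, SE 0.14, adjusted p = 5.46e-06), AGL65 rose by 1.48 and AGL104 by 0.88. The call of the list (camera adjusted p = 0.00763) was lost with an estimated correlation (adjusted p = 0.111), again with an estimate of −0.0055 and fewer degrees of freedom.

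Of 29 cell wall genes in TF2, 4 rose and 6 fell (4 and 6 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.672) or fry (adjusted p = 0.211). Its median, 0.58, and its mean, −0.08, differed in sign. XTH19 fell by 3.69, EXLA1 by 3.11, XTH18 by 2.89 and XTH32 by 2.24, on arrays where the leaf list and the actin and GAPDH 3′ controls were also low. Of 13 sugar transporters TMT1 (1.49) and SWEET1 (0.83) rose while SWEET8 (−2.33) and AtVEX1 (−0.75) fell, 2 and 2 adjusted over the list alone. That list was not called by camera (adjusted p = 0.778) or fry (adjusted p = 0.203), and camera's direction was down although the median was 0.18. ANX2 (0.93), ANX1 (0.81) and ACT12 (0.54) rose, 3 of 3 adjusted over the list alone, but after quantile normalization their median was 0.00424 and ANX2 turned to −0.02 (adjusted p = 0.928). MGH3, of 3 sperm and 2 histone genes, rose by 0.99 (1 gene of each list adjusted over the list alone).

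Of 4 cation and proton transporters in TF2, CHX6B (0.88), CHX15 (0.79) and chx28 (0.80) rose and CHX19 (−1.64) fell [3 higher, 1 lower]. AT5G48570, an FK506-binding co-chaperone gene also known as ROF2, was the 1 of 3 heat shock genes past the threshold, going from 668 ± 0.456 to 47.7 ± 18.9 (−3.59) [2 lower]. The nucleolar gene AT5G14520 fell by 3.02 [1 lower], the late embryogenesis abundant genes AT2G44060 by 1.77 and AT1G54410 by 0.69, of 4 [2 lower], the calmodulin-like gene CML38 by 1.86, of 2 defence genes [1 lower], and SWEET8 of 3 sporopollenin and tapetum genes [1 lower]. SGT rose (0.74), of 3 lipid metabolism genes [1 higher]. The 2 pectin-modifying genes, the lipid transfer gene and DFR did not pass the threshold [0 each].

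In limma 3506 of 11373 probe sets differed between TF2 and wild type, 1683 higher and 1823 lower, and 4585 had an unadjusted p under 0.05. Among those with 1 gene, 988 were higher and 814 lower. Over all called probe sets, 56 rose and 847 fell at least 4-fold. The count was 2185 (802 higher) without the trend, 2180 (964 lower) without wild type replicate 1 and 2113 (1118 higher, 995 lower) without wild type replicate 2. Median centring gave 2105 higher and 1521 lower, with the median change of all tested probe sets moved from 0.05 to 0.23 (0.14 under quantile normalization). Without the trend, ANX1, ANX2, ACT12, AGL104, AtVEX1, SWEET1, CHX15, chx28, SGT, AT2G44060 and AT1G54410 lost their calls. Leaving out a single array also ended those of AtVEX1, SWEET1, chx28, SGT, AT2G44060, AT1G54410 and CML38 in at least 1 case each.

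Changes in both lines ran largely in the same direction. Of the probe sets called in both comparisons, 1161 were higher in both lines and 908 lower in both, where independent lists of these sizes share 201 and 176. Across 11373 probe sets the log2 changes correlated at r = 0.759, with 0.500 on average and at most 0.520 in 100 simulations of unchanged groups sharing the wild-type arrays. Those simulations shared 0.03 calls on average and at most 1. The covariance was 0.788 against a simulated 0.110, a difference of 0.678. The simulations hold no real effects and the independent lists no shared controls. Part of the excess in shared calls may therefore come from the shared controls. The excess in r and in covariance is over simulations that already share those controls. Neither simulations nor independent lists cover a systematic difference of the wild-type samples, such as green tissue RNA, which would move both comparisons alike. After quantile normalization 1579 of 2451 calls in TF1 and 2677 of 3501 in TF2 held in the same direction. Opposite calls were made for 20 probe sets: 19 were higher in TF1 and lower in TF2, and AT1G70790 was lower in TF1 (−4.32) and higher in TF2 (1.14).

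**Figure D2:**
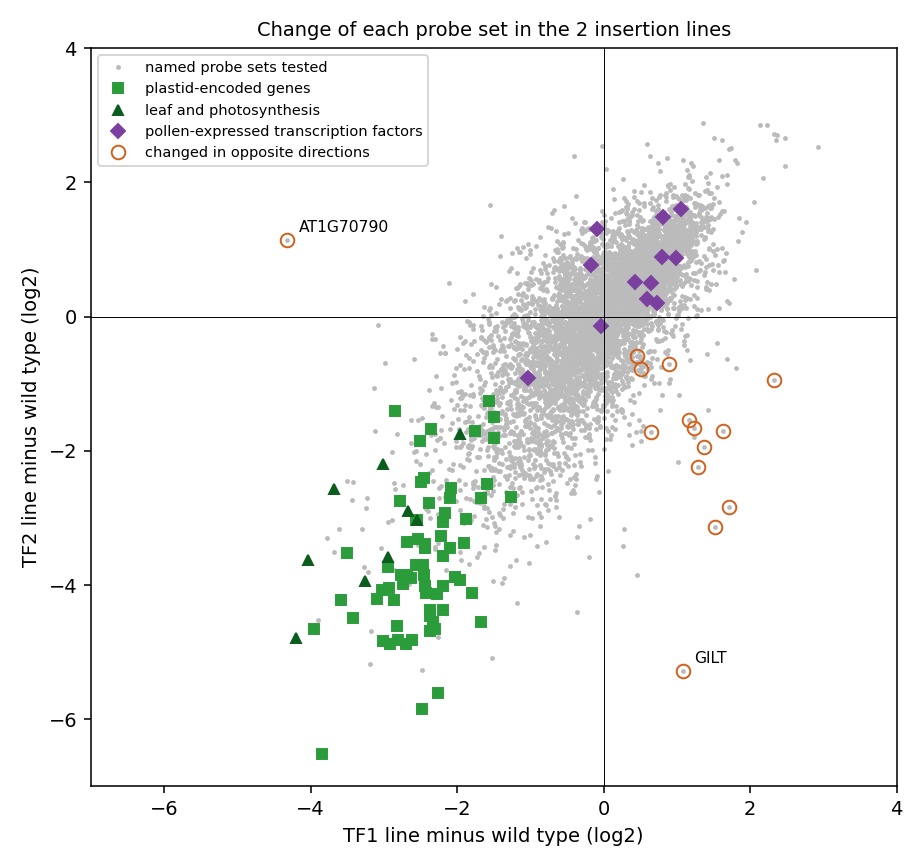
Log2 change against wild type of each tested probe set with 1 gene in the TF1 line (horizontal) and the TF2 line (vertical), with plastid-encoded genes, leaf genes, pollen transcription factors and named genes called in opposite directions marked. Leaf genes lie low on both axes (medians −3.02 and −3.03), plastid-encoded genes lie lower for TF2 (−3.85) than for TF1 (−2.44), and AT1G70790 stands apart at −4.32 and 1.14.

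The third comparison set the 2 lines against each other, which also tests where their differences from wild type are unequal. AT1G70790 read 26509 ± 1137 in TF2 against 594 ± 73.4 in TF1 (log2 change 5.46, SE 0.13, adjusted p = 2.32e-10), with wild type between them at 12012 ± 555. MT1C, a metallothionein gene, read 832 ± 156 in TF2 against 101 ± 37.9 in TF1 (2.95, SE 0.23, adjusted p = 1.68e-05). Among probe sets with 1 gene GILT was the steepest fall, at 24.5 ± 15.7 in TF2 against 2719.9 ± 477 in TF1 (−6.36, SE 0.26, adjusted p = 8.64e-08). The next largest falls among them were those of AT1G56100 (−4.66) and AT4G15750 (−4.55, 55.4 ± 31.3 against 1444 ± 20.2) of the pectin methylesterase inhibitor family, AT3G19690 (−4.31) of the CAP family, AT5G38170 (−4.03) of the lipid transfer protein superfamily, AT1G69840 (−3.69) and AT2G19970 (−3.56) of the CAP family.

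Among probe sets with 1 gene, the other largest falls in TF2 against TF1 were DELTA-VPE, a vacuolar processing protease gene known from the seed coat (−3.53), AT5G38180 (−3.44) and AT5G48570 (−3.39). The other largest rises among them were AT3G27325 (3.21), AT2G07724 (2.61), AT2G30660 (2.60), AT5G59170 (2.56), LIL3:2 (2.29), AT3G05050 (2.26), AT1G41600 (2.26) and AT5G38320 (2.19). Except for AT3G27325, each of these rises, and the fall of AT5G38180, lost its call under at least 1 alternative. SWEET8 (−1.25), EXLA1 (−1.63) and EXPA24 (−1.03) were lower in TF2, and SWEET1 (1.13), TMT1 (0.69), AGL65 (0.68), AGL18 (0.55) and CHX15 (0.53) were higher. Of these list genes, all lost their calls without the trend, and all but SWEET8 and EXPA24 when at least 1 of the arrays was left out.

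None of the 4 tested lists was called between the lines by camera, with 0 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry. The leaf list had 0 of 9 members past the threshold and a median of −0.24 (adjusted p = 0.725). Plastid-encoded genes, added after the values were seen, were lower in TF2 in 35 of 68 cases, with a median of −1.14 (camera adjusted p = 1.65e-29; adjusted p = 0.251 with an estimated correlation). Transcription factors had 2 of 12 higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.341), sugar transporters 2 higher and 1 lower of 13 (2 and 1; adjusted p = 0.341), and cell wall genes 2 of 29 lower (2; adjusted p = 0.341). Other members past the threshold were AT5G48570 of the heat shock list [2 lower], AT2G46140 of the late embryogenesis abundant list (−0.51) [2 lower], SWEET8 of the tapetum list [1 higher, 1 lower] and CHX15 of the cation and proton list [1 higher].

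**Figure D3:**
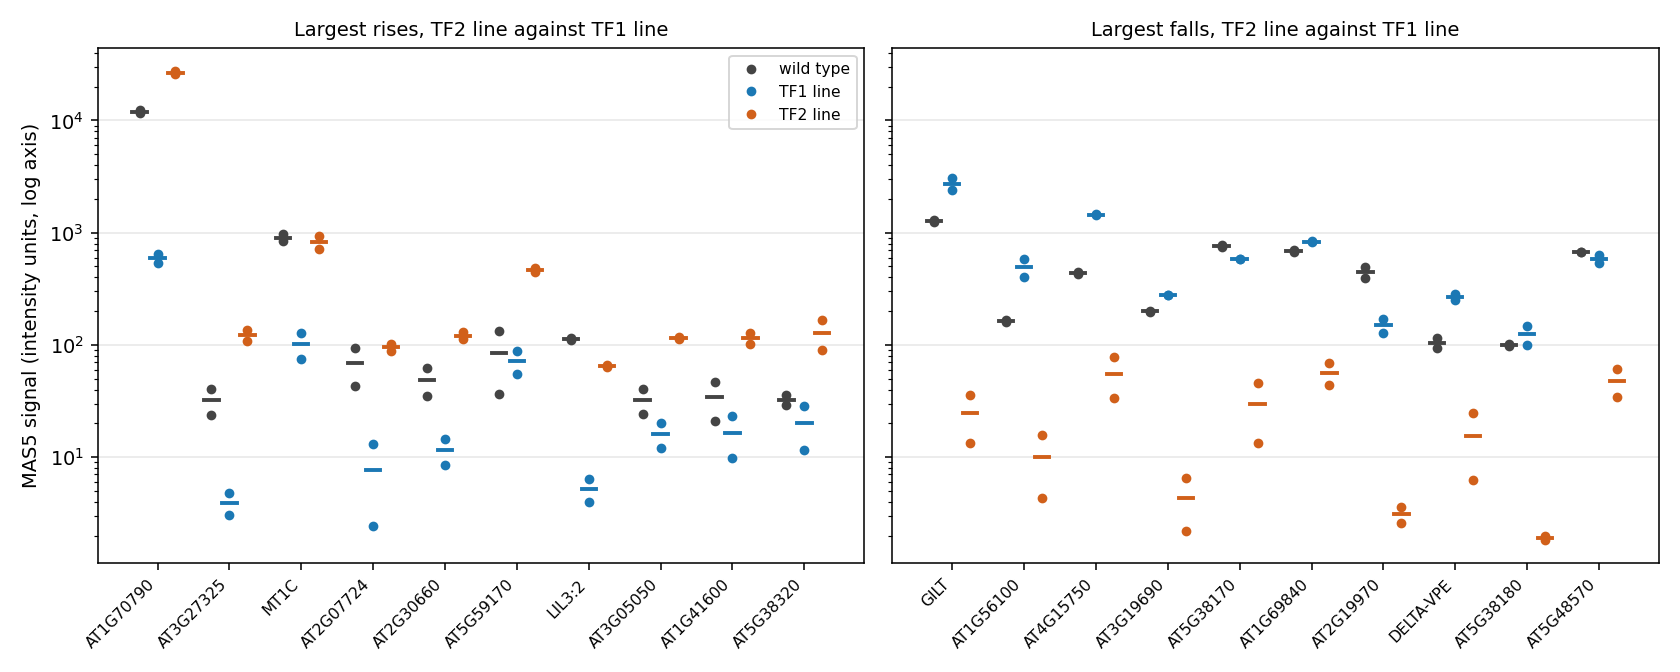
Array signal (intensity units, log axis) of the 10 named genes with the largest rises and the 10 with the largest falls in the TF2 line against the TF1 line; points are arrays, bars are means of 2 arrays. AT1G70790 averaged 12012 in wild type, 594 in TF1 and 26509 in TF2, and GILT averaged 1275, 2719.9 and 24.5.

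Between the lines 529 of 11373 probe sets differed in limma, 97 higher and 432 lower in TF2, and 2101 had an unadjusted p under 0.05. Of these, 387 were lower in TF2 than in both other groups, 61 of them with TF1 not lower than wild type, and 22 were lower in TF1 than in both. In addition, 60 were higher in TF2 than in both and 52 higher in TF1 than in both, and these sets overlap: AT1G70790 was lower in TF1 and higher in TF2 than in both others. The count was 175 without the trend (19 higher, 156 lower), 252 with only the 2 lines in the fit (51, 201), 285 (44, 241) and 291 (45, 246) without wild type replicates 1 and 2, and 222 (51, 171) and 217 (42, 175) without TF1 line replicates 1 and 2. The higher count was also 36 and 51 without TF2 line replicates 1 and 2, 48 without the filter and 55 with median centring.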

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

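All tests of explanations in this part were chosen only after the results were seen.

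Signal in the control probe sets, which the comparisons leave out, lay far above wild type in some samples. The probe set for 25S ribosomal RNA averaged 9342 ± 885 in the TF2 line against 401 ± 109 in wild type, with the dimmer TF2 array 18.2-fold above the brighter wild-type array, and it read 260.2 and 2749 on the TF1 arrays. The probe set for 5S ribosomal RNA went the other way, at 584 and 447 in wild type, 206.0 and 128 in TF1, and 72.3 and 38.2 in TF2. The control probe set AFFX-r2-At-U12639_at, whose target is not given in the sources used here, averaged 1870.2 ± 383 in the TF1 line, read 2.15 and 35.8 on the wild-type arrays, and read 26.4 and 19.0 in TF2.

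The lines differed in opposite directions from wild type for 20 probe sets, and the comparison of TF2 with TF1 tested the difference itself. Among those higher in TF1 and lower in TF2 were GILT (1.08 and −5.28), AT4G15750 (1.71 and −2.84) and AT1G56100 (1.52 and −3.14). The widest gap between the lines upward was that of AT1G70790, at 5.46.

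The leaf list and plastid-encoded genes lay lower in both lines than in wild type. Poor labelling of RNA without a poly(A) tail was argued against as the cause of the leaf list's fall. That list is nuclear and fell by 3.02 in the line where it moved least. It holds no plastid-encoded genes, so it cannot tell whether poor labelling had a part in their fall. Against the authors' scaling, the leaf list's median stayed at −2.94 after quantile normalization. More green tissue RNA in TF1 than in TF2 was argued against as the cause of the further plastid fall. Plastid minus nuclear leaf signal moved by −1.33 from TF1 to TF2 (SD between replicates 0.252). This used 59 plastid and 6 leaf genes with a TF1 mean of at least 4 times the pseudocount, a choice made on TF1 alone. The argument holds only if the leaf signal left in the lines came from green tissue, which was not tested. Poor labelling of RNA without a poly(A) tail in TF2 was not tested as a cause of this further fall. Green tissue RNA in the wild-type samples cannot be told apart from an effect of the genotypes, because leaf list signal followed the groups: its mean log2 signal on the lowest wild-type array lay 2.97 above that on the highest array of the lines.

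AT1G70790 was low in the TF1 line and not in TF2. Green tissue RNA in wild type was argued against as the cause, because the gene was 1.14 higher in TF2 than in wild type while the leaf list was as low there as in TF1. Loss of a chromosome segment spanning several genes was argued against by the nearest measured genes, 2 genes away on either side. AT1G70780 changed by −0.66 (limma adjusted p = 0.0286) and AT1G70810 by 0.46. The 10 nearest measured genes had a median of −0.43 (SE of their mean, over genes, 0.19). These reached as far as AT1G71040, 35 genes away, so their median could not show a short loss. The genes directly beside AT1G70790 were not measured. What stays open is an effect of the insertion in TF1 on this gene, or a difference in that seed stock at the gene. A difference that also takes in the genes directly beside it stays open too. None of these was tested.

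A set of 61 probe sets was lower in TF2 than in both other groups with TF1 not lower than wild type, and it held BAN and DELTA-VPE, genes known from the seed coat. Green tissue RNA in wild type and TF1 would also lower the leaf list in TF2 against TF1, but that list changed by −0.0061 on average. By definition the set leaves out genes that, like the leaf list, were lower in TF1 than in wild type. The leaf value is thus no separate test of the set. Loss of a chromosome segment in TF2 was argued against, as no more than 2 of the 35 named genes lay within 100 neighbouring genes. Seed coat RNA in the wild-type and TF1 samples cannot be told apart from an effect of the insertion. The 5 measured seed coat markers outside the set, from a list of 29 drawn up after the pattern was seen, had a median of −0.93 between the lines (4 of 5 negative, 0 past limma's adjusted threshold; AT5G49180 at −1.94, SWEET11 at 0.68). Limma's rotation test fry called these markers lower as a set (adjusted p = 0.0113, with 1 list tested). Fry sets them against no other genes, and an effect of the insertion could lower them too. It therefore favours neither explanation, and 5 markers that differ in direction are too few to decide.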

How the results depend on the processing

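The fit without organelle-encoded and leaf list genes was chosen only after the results were seen; the other alternatives were planned. Of 119 named gene results, 67 kept direction and call in every alternative that gave a value; over 1851 alternative values 1637 did so, 213 lost the call and 1 turned, ANX2 in TF2 against wild type under quantile normalization (−0.0193). Of the lost calls 45 came without the trend, 16 under quantile normalization, 13 without the filter and 104 with an array left out. By camera at the preset correlation, the leaf and transcription factor lists stayed called against wild type in each alternative whose calls were kept by list. The 2-group fits kept only the number of lists called, and the leaf list was not tested where its genes were left out. With an estimated correlation 1 list was called in TF1 and 1 in TF2, the leaf list. Fry called 4 in TF1 and 2 in TF2. As fry does not compare a list with other genes, its calls do not show that a list stood out from them. How much each difference between the tests mattered was not tested.

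Without the trend the counts were 456 (75 higher, 381 lower) for TF1, 2185 (802 higher) for TF2 and 175 (19 higher, 156 lower) between the lines; a pooled prior in place of a trended one was the only change. With only the 2 lines fitted, which leaves fewer samples, 252 differed (51 higher, 201 lower). The higher count between the lines was 48 without the filter, where more probe sets are tested, and 55 under median centring; the cause was not tested. The correlation of changes was 0.723 and 0.815 with the smaller and larger pseudocount, 0.698 without the filter and 0.848 in the brightest 25%; the cause was not tested. BZIP34 in TF2 against wild type lost its call at 1.44 with the smaller pseudocount, at 1.304 without the filter and at 1.304 without the trend.

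With an array left out, TF1 against wild type ranged over 1266 to 2817 (819 to 1420 higher, 415 to 1397 lower), TF2 over 2113 to 3543 (1118 to 1672 higher, 964 to 1871 lower) and the lines against each other over 217 to 589 (36 to 51 higher, 171 to 538 lower). BZIP34 ranged from 1.04 to 1.57 and the correlation from 0.694 to 0.764. The lone sample left in a group was assumed to vary like the others. Without organelle-encoded and leaf list genes 2350, 3410 and 479 probe sets differed. Dim genes are limited by the pseudocount, 10.3, below which the scale flattens.

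The labels give all groups the same replicate numbers. Deviations of same-numbered arrays correlated at 0.00794, 0.0216 and 0.00204, so no shift shared by same-numbered arrays was seen. Whether same-numbered samples were collected or processed together is not known from this. With the replicate block 2521, 3558 and 593 probe sets differed, and 2409, 3436 and 516 of the calls above were among them.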

Other observations

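The family lists and the genes in this part were chosen only after their values were seen, and the tests here were chosen then too.

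Other groups moved on the same arrays. Of 12 mitochondrion-encoded genes, 6 fell in TF1 (median −1.46) and 10 in TF2 (median −2.12), with camera adjusted p of 3.39e-06 and 1.55e-06, both lost with an estimated correlation (adjusted p = 0.209 and 0.250). Of 8 aldehyde dehydrogenase genes, 2 fell in TF1 and 3 in TF2 (camera adjusted p = 0.00449 and 0.0215; adjusted p = 0.209 and 0.352 with an estimated correlation). ALDH10A8 read 202 ± 36.5 in wild type, 76.9 ± 9.18 in TF1 and 5.79 ± 1.36 in TF2, and it was lower in TF2 than in TF1 (−2.43). ALDH11A3 was lower in TF1 (−2.15) and TF2 (−2.44), and after quantile normalization too (−1.98 and −2.35). Of 5 EXPA expansin genes 3 rose in TF1 (camera adjusted p = 0.0193; adjusted p = 0.255 with an estimated correlation) and 1 in TF2 (camera adjusted p = 0.539; adjusted p = 0.764 with an estimated correlation). Of the 20 added lists large enough to test, camera called 5 in TF1 against wild type, 4 in TF2 and 1 between the lines, and 0 with an estimated correlation.

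Some of the brightest pollen transcripts were higher in both lines on the deposited scaling. The signal peptide gene RALFL26 read 14663 ± 625 in wild type, 26121 ± 1111 in TF1 and 30129 ± 3543 in TF2 (log2 changes 0.83 and 1.03), and RALFL25 moved by 0.75 and 0.81. The beta-tubulin gene TUB9 (0.81 and 1.14) and the defensin-like gene LCR72 (0.79 and 1.08) moved alike. After quantile normalization these changes were 0.05 and 0.13 for RALFL26, −0.08 and −0.12 for RALFL25, 0.05 and 0.24 for TUB9 and 0.04 and 0.18 for LCR72, and none passed the threshold. Dimmer relatives went the other way: RALFL33 fell from 335 ± 7.60 to 43.8 ± 42.9 in TF1 and 19.4 ± 18.3 in TF2, and kept its calls after quantile normalization (−2.68 and −3.56). LCR69 fell in TF2 against wild type (−3.37) and against TF1 (−2.58).

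Outside the rule for named genes, BAN, an enzyme gene of seed coat tannin synthesis, was higher in TF1 (1.63) and lower in TF2 (−1.71) than in wild type. CHIL, of flavonoid synthesis, was lower in TF2 than in wild type (−1.79) and TF1 (−3.03).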
